A study of Mus musculus with 12 samples.

How the data were processed

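The series holds RNA sequencing of SCC7 mouse squamous carcinoma cells in 12 libraries, 3 for each of 4 conditioned media of bone-marrow-derived macrophages (M0 CM, M1 CM, M2 CM and TAM CM). Per the labels' protocols, macrophages were treated for 24 h, SCC7 cells were kept in the conditioned medium for 24 h, RNA was taken with Trizol, and mRNA libraries were made by a standard Illumina protocol. The deposited file gives raw read counts per Ensembl gene for each library, with no scaling. HISAT2 2.0 and genome build mm10 are named in the submitters' processing notes. The counting tool, the annotation release and the strand setting are not given in the sources used here. Whether the cytokines or the SCC7 medium were taken off before the macrophage medium was collected is not given in the sources used here. Libraries were grouped by their titles. The cell type in the label of the third M2 CM library is a melanoma, and the library was kept in M2 CM, with every comparison that uses it also run without it.

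The file holds 55487 genes, of which 55141 were matched by Ensembl identifier to a symbol of GENCODE release M21 (GRCm38), which also gave the mm10 coordinates. That release may not be the one used by the authors. Library totals ran from 18996937 to 22596630 counts. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr on the groups (14509 genes; the genes removed held 0.0815% of the counts), scaled by TMM and fitted with glmQLFit (robust) with a mean for each group and no other term. The 6 comparisons between groups were tested by glmQLFTest, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the log2 fold change over the square root of the F statistic. For a large fold from a group well under 1 CPM, this standard error understates the counting error of that group. At this depth 1 CPM is about 20 counts in a library, so values well under 1 CPM rest on few counts. Where a group had no counts the fold is given as a bound, with a floor of 3 counts over the group. Where it had 1 to 3 counts the ratio is given with an exact binomial 95% interval. CPM values use TMM-scaled library sizes, and principal components were taken of log2 CPM with a prior count of 2.

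Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists with at least 5 tested members, which were 23 of 24 pathway lists. The list of MHC class II antigen presentation had 3. Some genes are on several lists, so the calls of those lists are not independent of each other. Camera was repeated with a correlation estimated for each list, and fry was run as a self-contained test. The 8 lists of cell type markers were read as summed CPM and were not tested as lists. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined.

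Genes named in the report follow that rule. Against M0 CM it takes the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, at least 2 CPM in the higher group and no overlap between groups, without predicted genes, and for the other comparisons 6 and 6. It adds up to 4 members with the smallest p of each list called, up to 2 of other lists and of cell type lists, and a panel of 15 genes. The report prints a part of the genes so named, and 2 of them are not reported here and were left out of the alternatives for named genes.

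The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in the edgeR fit, other filters for low counts, fits of only the 2 groups compared, the replicate number as a term of the model, glmTreat against a 1.5-fold change, and each library left out in turn. Library sizes with no scaling factors were added after the values had been seen. The steps were tested on simulated counts with 200 genes changed between M1 CM and M0 CM. The edgeR test recovered 34, 46, 50 and 50 of 50 genes at folds of 1.25, 1.5, 2 and 4 and called 9 of 13690 unchanged genes. Camera called the 1 list shifted 1.5-fold and 0 of 22 others. The simulated genes were drawn independently and only the shifted list changed, so this gives no test of the preset correlation. The 200 genes were changed in M1 CM only, as many up as down, with dispersions taken from the main fit. In the real libraries 39.4% to 70.0% of genes were called per comparison. The simulation gives no test of scaling or of false calls in that setting. Sharing of calls was compared with 20 simulated data sets in which all groups had the M0 CM means and shared its libraries. Figures were drawn with matplotlib 3.10.9.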

Results

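Gene expression was measured by RNA sequencing in SCC7 cells, a mouse squamous cell carcinoma line, after 24 h in medium conditioned by macrophages. The macrophages were derived from mouse bone marrow and had first been kept for 24 h in 1 of 4 ways. Control medium gave M0 conditioned medium (M0 CM). Interferon-gamma at 20 ng/ml gave M1 CM, and interleukin-4 at 20 ng/ml gave M2 CM. A mixture holding 75% medium conditioned by SCC7 cells gave TAM CM, named for tumour-associated macrophages. Each of the 4 groups had 3 libraries, 12 in all, and the RNA was that of the SCC7 cells. Total counts per library ran from 18996937 to 22596630, and 14509 of the 55487 genes in the count table passed the expression filter.

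Values are given below as CPM on TMM-scaled library sizes, as mean ± SD of n = 3 libraries. Fold changes carry their standard error (SE), and gene calls are from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The biological coefficient of variation over all 12 libraries was 3.65%. Within each group, Pearson's r of log2 CPM across genes lay between 0.992 and 0.994 for every pair of libraries, genes not being independent replicates. No pair was identical, and the chi-square over its degrees of freedom lay between 2.00 and 5.17.

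The 4 groups separated from each other on the principal components of log2 CPM. The first component held 46.6% of the variance and set the TAM CM libraries apart. The second held 33.3% and set the M1 CM libraries apart, and the third, with 7.56%, lay between M0 CM and M2 CM. Mitochondrial genes took 1.78 ± 0.0252% of the counts in M0 CM, 1.69 ± 0.0552% in M1 CM, 1.75 ± 0.0372% in M2 CM and 1.70 ± 0.0499% in TAM CM.

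**Figure D1:**
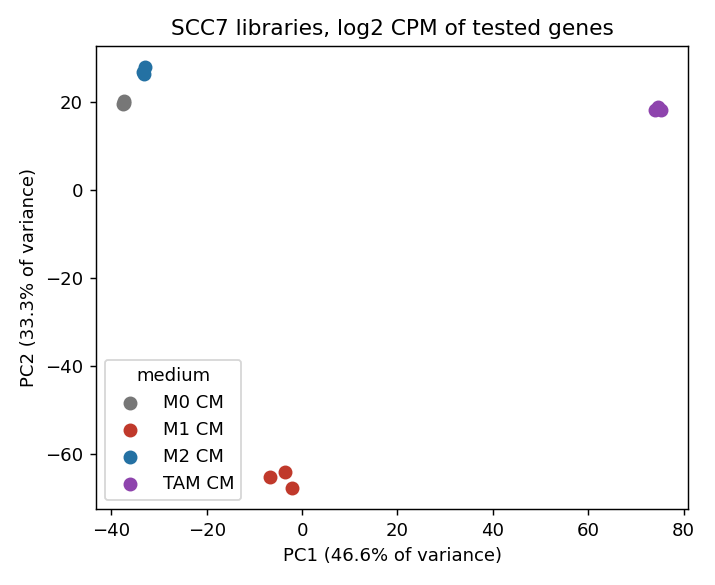
Principal components 1 and 2 of log2 CPM over the 14509 tested genes, each point a library coloured by the medium the SCC7 cells were kept in. Component 1 (46.6% of variance) separates the 3 TAM CM libraries and component 2 (33.3%) the 3 M1 CM libraries from the rest.

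Marker lists of other cell types were read as summed CPM. The macrophage list stood at 27.7 ± 0.999 CPM in M0 CM, 42.2 ± 3.81 in M1 CM, 28.7 ± 1.59 in M2 CM and 51.6 ± 4.39 in TAM CM. Most of it was Cd14, a lipopolysaccharide co-receptor, at 17.3 ± 0.898 CPM in M0 CM and 40.9 ± 3.80 in TAM CM. The fibroblast list, which includes collagens that the SCC7 cells expressed in every group, was at 2573 ± 77.4 CPM in M0 CM and lower in the other groups, at 1483 ± 52.9 in M1 CM, 1514 ± 14.9 in M2 CM and 1172 ± 32.2 in TAM CM. The melanocyte list was at 8.28 ± 1.07 CPM in M0 CM, 11.3 ± 1.58 in M1 CM, 6.62 ± 0.824 in M2 CM and 11.8 ± 0.895 in TAM CM, nearly all of it Mitf. The T and NK cell, B cell, neutrophil, endothelial and erythroid lists were each below 3 CPM in all groups, with the highest sum, 2.20 ± 0.517 CPM, for neutrophil markers in M1 CM. The third M2 CM library carries a melanoma cell type in its label, where the other 11 libraries carry squamous carcinoma, and was kept in M2 CM. Its melanocyte sum was 6.80 CPM, beside 7.34 and 5.72 in the first and second M2 CM libraries. Pearson's r of its log2 CPM with each of them was 0.9935. These values argue against another cell line in this library.

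Comparing M1 CM with M0 CM asks how SCC7 cells respond to medium from macrophages treated with interferon-gamma. Interferon-responsive genes rose together and by the largest folds. Cxcl9, a chemokine that attracts T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079 in mm10), went from 0.0610 ± 0.0208 to 400.3 ± 20.2 CPM, a log2 fold change of 12.52 (SE 0.11). The SE of Cxcl9 understates the counting error of its M0 CM mean, which rests on few counts. The chemokine gene Cxcl10 went from 23.1 ± 1.12 to 901 ± 62.5 CPM. Cd274, which encodes the immune checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), rose from 0.504 ± 0.265 to 51.4 ± 2.59 CPM, 99.2-fold, with an edgeR quasi-likelihood adjusted p of 1.58e-37.

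All 27 tested members of the interferon-gamma response list rose, with a median log2 fold change of 5.43 (camera adjusted p = 7.81e-32). They include the GTPase genes Iigp1, at 1206 ± 26.2 against 0.319 ± 0.137 CPM, and Gbp4, at 2138 ± 39.7 against 49.0 ± 1.80 CPM. All 32 tested members of the type I interferon list rose as well (median 4.93, camera adjusted p = 6.43e-32), among them the nucleic acid sensor Zbp1, at 371 ± 7.64 against 0.817 ± 0.120 CPM, and Stat2, at 340 ± 8.88 against 25.7 ± 1.82 CPM. Every one of the 19 tested genes for MHC class I antigen presentation rose (median 1.98, camera adjusted p = 3.02e-25). B2m, the class I light chain, went from 615 ± 7.05 to 2427 ± 60.3 CPM, Tap1, part of the peptide transporter, from 31.5 ± 2.71 to 408 ± 3.31 CPM, and H2-K1 from 234 ± 8.21 to 804 ± 33.5 CPM. Only 3 members of the MHC class II list could be tested, too few for a list test; Cd74 rose from 0.126 ± 0.0358 to 0.911 ± 0.169 CPM and Ifi30 fell from 30.6 ± 0.958 to 25.7 ± 1.47 CPM.

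Inflammatory lists moved the same way, and some share members with each other or with the interferon-gamma list. Cxcl9, Cxcl10 and Cd274 are among the shared members, so these calls are not independent. Of 22 genes on the NF-kB and TNF list 20 rose and 1 fell (median 1.24, camera adjusted p = 4.34e-14), with Sod2, a mitochondrial superoxide dismutase, at 375 ± 11.9 against 87.0 ± 1.59 CPM. Of 27 chemokine and cytokine genes 20 rose and 3 fell (median 2.82, camera adjusted p = 5.06e-09); Ccl5 was at 218 ± 18.1 against 7.20 ± 0.239 CPM and Ccl2 at 1804 ± 294 against 233 ± 10.7 CPM. All 13 tested genes of the STAT3 and acute phase list rose (median 1.48, camera adjusted p = 2.33e-10), including the iron-binding Lcn2, at 24.5 ± 1.27 against 0.704 ± 0.215 CPM. The immune checkpoint list had 8 genes higher and 1 lower of 11 (median 0.58, camera adjusted p = 0.000876), among them Lgals9 at 111 ± 7.68 against 56.0 ± 2.09 CPM. Complement genes were 7 higher and 3 lower of 11 (median 1.504, camera adjusted p = 0.00204; adjusted p = 0.0979 with an estimated correlation), with C3 at 747 ± 46.4 against 130 ± 7.17 CPM.

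Genes of amino acid supply and the integrated stress response were also higher, 23 of 25 tested rising and none falling (median 1.503, camera adjusted p = 6.37e-20). Asns, which makes asparagine, went from 85.7 ± 0.501 to 268 ± 16.5 CPM, and Slc3a2, the heavy chain of amino acid transporters, from 123 ± 5.14 to 284 ± 18.1 CPM. Lysosome and iron genes were 14 higher and 2 lower of 16 (median 0.36, camera adjusted p = 9.84e-07). The NRF2 list had 10 higher and 3 lower of 20 (median 0.15, camera adjusted p = 0.002; adjusted p = 0.403 with an estimated correlation). The MAPK and AP-1 list had 14 higher and 2 lower of 25 (median 0.35, camera adjusted p = 0.00204; adjusted p = 0.27 with an estimated correlation).

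Proliferation and sterol genes were lower in M1 CM. Of 30 cell cycle genes 29 fell and none rose (median -0.35, camera adjusted p = 5.46e-14), and the proliferation marker Mki67 went from 877 ± 13.9 to 504 ± 12.9 CPM. Cholesterol synthesis genes were 18 lower and 2 higher of 22 (median -0.52, camera adjusted p = 4.78e-08). The TGF-beta and BMP list had 12 lower and 3 higher of 18 (median -0.53, camera adjusted p = 0.000362), with Id2 at 33.6 ± 4.10 against 113 ± 1.02 CPM. Epithelial junction and keratin genes were 7 lower and 2 higher of 11 (median -1.05, camera adjusted p = 0.00802; adjusted p = 0.0507 with an estimated correlation), with Krt8 at 129 ± 1.52 against 267 ± 8.57 CPM. Glycolysis and hypoxia genes were 19 lower and 6 higher of 30 (median -0.25, camera adjusted p = 0.00171; adjusted p = 0.406 with an estimated correlation). Genes of the unfolded protein response of the endoplasmic reticulum were 11 lower and 3 higher of 18 (median -0.16, camera adjusted p = 0.00811; adjusted p = 0.268 with an estimated correlation).

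In all, 4023 genes were higher and 3719 lower in M1 CM than in M0 CM by edgeR's quasi-likelihood test, of which 852 and 389 differed at least 2-fold. With library sizes alone in place of TMM factors the split was 3219 higher and 4626 lower. The values of the groups did not overlap for 8531 genes, where chance gives 10% of genes for 3 libraries against 3. Serpina3f, a serine protease inhibitor, had no counts in M0 CM and was at least 263-fold higher in M1 CM (floor of 3 counts over the group). Of the genes that fell, Col12a1, a fibril-associated collagen, went from 83.4 ± 8.13 to 7.56 ± 0.134 CPM. Camera called 18 of the 23 lists tested, and 12 of these calls held with an estimated correlation. The lists it did not call were IL-4 and STAT6 (5 higher and 6 lower of 11), epithelial-mesenchymal transition (10 and 9 of 23, with a median of 0.02 that turned negative with library sizes alone and a camera direction already down), cancer stem cell markers (6 and 4 of 12), p53 targets (10 and 6 of 18) and oxidative phosphorylation (12 and 7 of 27). The IL-4 list's median was -0.15 and its mean 0.47. For cancer stem cell markers the camera adjusted p of 0.062 ranged from 0.0267 to 0.0742 over 9 other scalings, models and libraries left out. This list passed without M0 CM 1, 2 or 3 (0.0413, 0.0467 and 0.0374), without M1 CM 2 (0.0267), and with library sizes alone (0.0438). Adjusted over the list alone, the counts were the same as those over all genes tested except for 1 more lower gene on the unfolded protein list and 1 more higher gene on the TGF-beta list. The members of the Gbp, Ifit, Oas, Tgtp, Serpina3 and H2 families share reads with near copies and are uncertain one by one, as are antisense and overlapping genes, since no strand setting is given in the sources used here.

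M2 CM against M0 CM puts the same question for medium from macrophages treated with interleukin-4, and fewer genes passed the test. Interleukin-4 left in the medium was not separated from macrophage products in these groups. Il24, a cytokine of the interleukin-10 family (ENSMUSG00000026420, chromosome 1, 130882074 to 130887454), rose from 0.0757 ± 0.0670 to 54.8 ± 2.48 CPM. Its log2 fold change was 9.36 (SE 0.21) with an edgeR quasi-likelihood adjusted p of 1.48e-34. This SE understates the counting error of the M0 CM mean, which rests on few counts. Il13ra2, a decoy receptor for interleukin-13 (chromosome X, 147383476 to 147429192), was at 12.8 ± 0.212 against 0.0468 ± 0.0038 CPM, a ratio of counts of 275 with an exact 95% interval from 93.9 to 1338, which covers counting error only. Lipg, an endothelial lipase, rose from 5.39 ± 0.621 to 172 ± 6.36 CPM, and Ces1g, a carboxylesterase of a multi-copy family, from 5.07 ± 0.489 to 101 ± 7.06 CPM. Of the genes that fell, Pdgfrb, a platelet-derived growth factor receptor, went from 40.7 ± 1.502 to 7.71 ± 0.457 CPM.

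The list on which the M2 CM call also held with an estimated correlation was NF-kB and TNF, where 16 of 22 genes rose and 1 fell (median 0.26, camera adjusted p = 6.36e-07; adjusted p = 0.033 with an estimated correlation). On it, Nfkb1, which encodes the p105 precursor of an NF-kB subunit, rose from 167 ± 1.59 to 568 ± 1.77 CPM. On the IL-4 and STAT6 list 7 of 11 genes rose and 3 fell (median 0.43, camera adjusted p = 0.0327; adjusted p = 0.214 with an estimated correlation). Socs1, a feedback inhibitor of cytokine signalling, rose from 19.02 ± 1.58 to 63.3 ± 6.38 CPM, Postn from 9.95 ± 0.727 to 32.0 ± 2.24 CPM and Cish from 0.814 ± 0.424 to 4.62 ± 0.0502 CPM, while the cadherin gene Cdh26 fell from 88.1 ± 3.51 to 32.5 ± 0.987 CPM. Chemokine and cytokine genes were 9 higher and 3 lower of 27 (median 0.74, camera adjusted p = 0.00156; adjusted p = 0.0783 with an estimated correlation), with Ccl7 at 458 ± 5.79 against 149 ± 0.944 CPM. STAT3 and acute phase genes were 8 higher and 2 lower of 13 (median 0.23, camera adjusted p = 0.0124; adjusted p = 0.167 with an estimated correlation).

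Stress and growth lists shifted by small amounts. Amino acid and integrated stress response genes were 20 higher and 2 lower of 25 (median 0.46, camera adjusted p = 9.82e-08; adjusted p = 0.32 with an estimated correlation), with Asns at 120 ± 2.87 against 85.7 ± 0.501 CPM. Unfolded protein response genes were 13 higher and 1 lower of 18 (median 0.19, camera adjusted p = 1.7e-05; adjusted p = 0.167 with an estimated correlation); the chaperone gene Hspa5 was at 1187 ± 59.5 against 823 ± 19.1 CPM. Cell cycle genes were 19 higher and 4 lower of 30 (median 0.12, camera adjusted p = 0.00344; adjusted p = 0.428 with an estimated correlation), although Mki67 itself fell from 877 ± 13.9 to 773 ± 10.3 CPM. The p53 targets were 9 higher and 3 lower of 18 (median 0.24, camera adjusted p = 0.0143; adjusted p = 0.32 with an estimated correlation). MAPK and AP-1 genes were 11 higher and 2 lower of 25 (median 0.23, camera adjusted p = 0.0067; adjusted p = 0.428 with an estimated correlation). Oxidative phosphorylation genes were 11 higher and 0 lower of 27 (median 0.10, camera adjusted p = 0.0219; adjusted p = 0.428 with an estimated correlation). That call was lost without M2 CM 2 (adjusted p = 0.0591) and with library sizes alone (adjusted p = 0.108, 5 genes higher and 4 lower), the upper end of its range over these settings. TGF-beta and BMP genes were 8 lower and 3 higher of 18 (median -0.12, camera adjusted p = 0.00432; adjusted p = 0.167 with an estimated correlation). MHC class I genes were 8 lower and 1 higher of 19 (median -0.15, camera adjusted p = 0.00853; adjusted p = 0.448 with an estimated correlation).

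Several genes that rose in M1 CM did not pass the test here. Cd274 was at 0.429 ± 0.195 against 0.504 ± 0.265 CPM and Cxcl10 was at 26.2 ± 1.40 against 23.1 ± 1.12 CPM, where Cxcl10 passed in a fit of these 2 groups only (edgeR quasi-likelihood adjusted p = 0.0291 in place of 0.191). The interferon-gamma list had 4 genes higher and 11 lower of 27 (median -0.23). Its camera adjusted p was 0.0637, and it passed without M0 CM 1 (0.0496) or M2 CM 2 (0.0412). The type I interferon list had 3 higher and 12 lower of 32 (median -0.29, camera adjusted p = 0.0712). The keratins Krt8 and Krt18 rose, from 267 ± 8.57 to 453 ± 20.5 CPM and from 105 ± 6.80 to 263 ± 19.2 CPM. The epithelial list was even, with 3 genes higher and 3 lower of 11 (median -0.22, mean 0.04). Lists without a call also included cholesterol synthesis (5 higher and 4 lower of 22), epithelial-mesenchymal transition (7 and 8 of 23, median -0.02 and mean 0.04), glycolysis (8 and 8 of 30), NRF2 (6 and 7 of 20), complement (2 and 3 of 11, median -0.20 and mean 0.03), checkpoint ligands (4 and 2 of 11), cancer stem cell markers (4 and 2 of 12) and lysosome (5 and 6 of 16).

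By edgeR's quasi-likelihood test 3042 genes were higher and 2681 lower in M2 CM than in M0 CM, with 220 and 251 of them at least 2-fold apart, and 7182 genes did not overlap between the groups against 10% by chance. With library sizes alone the split was 2201 higher and 3653 lower. Without the third M2 CM library, whose label names melanoma, 2711 were higher and 2413 lower. Camera called 12 lists, 1 of them with an estimated correlation. Adjusted over the list alone, the counts differed from those over all genes by 1 more lower gene on the STAT3 and the epithelial-mesenchymal lists, 3 more on the epithelial junction list, and 1 more higher gene on the p53 and the lysosome lists.

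Comparing TAM CM with M0 CM asks how the cells respond to medium from macrophages that had been kept in tumour cell medium. No group had medium of SCC7 cells without macrophages. SCC7 medium left over was therefore not separated from macrophage products, for any difference of TAM CM from the other groups. Genes of amino acid supply and the integrated stress response were higher (camera adjusted p = 3.49e-19; adjusted p = 0.111 with an estimated correlation), and cholesterol synthesis genes were lower. Slc3a2 (ENSMUSG00000010095, chromosome 19, 8706882 to 8723369) went from 123 ± 5.14 to 1005 ± 20.7 CPM, a log2 fold change of 3.03 (SE 0.04) with an edgeR quasi-likelihood adjusted p of 3.15e-46. Hmgcs1, an early enzyme of cholesterol synthesis (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), fell from 231 ± 4.42 to 32.5 ± 0.808 CPM, a log2 fold change of -2.83 (SE 0.04). Hmox1, which breaks down haem (chromosome 8, 75093621 to 75100589), rose from 108 ± 5.91 to 1870 ± 204 CPM, and Myc, a growth-promoting transcription factor, from 111 ± 6.20 to 843 ± 24.1 CPM.

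All 25 tested members of the amino acid and integrated stress response list rose, with a median log2 fold change of 3.03 (camera adjusted p = 3.49e-19; adjusted p = 0.111 with an estimated correlation). Asns went from 85.7 ± 0.501 to 523 ± 13.3 CPM, Phgdh, the first enzyme of serine synthesis, from 376 ± 3.13 to 1278 ± 38.4 CPM, and the cationic amino acid transporter Slc7a1 from 137 ± 3.23 to 619 ± 21.4 CPM. All 22 tested cholesterol synthesis genes fell (median -2.14, camera adjusted p = 1.22e-15; adjusted p = 0.0302 with an estimated correlation); Stard4, a sterol carrier, went from 147 ± 2.51 to 22.6 ± 1.01 CPM. The unfolded protein list split, with 9 genes higher and 8 lower of 18 and no call (median 0.07, negative with library sizes alone; camera adjusted p = 0.137). Its members Hspa5 and Herpud1 rose, from 823 ± 19.1 to 2849 ± 58.8 CPM and from 52.4 ± 2.59 to 286 ± 4.11 CPM.

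Other stress lists were higher. NRF2 genes were 15 higher and 1 lower of 20 (median 0.72, camera adjusted p = 7.18e-05; adjusted p = 0.396 with an estimated correlation), with Txnrd1, a thioredoxin reductase, at 992 ± 26.5 against 493 ± 14.5 CPM. The p53 targets were 13 higher and 4 lower of 18 (median 0.76, camera adjusted p = 0.0045; adjusted p = 0.238 with an estimated correlation), with Sesn2, also on the amino acid list, at 307 ± 9.15 against 47.9 ± 2.29 CPM. MAPK and AP-1 genes were 17 higher and 3 lower of 25 (median 0.79, camera adjusted p = 0.00114; adjusted p = 0.36 with an estimated correlation); Areg, a ligand of the EGF receptor, was at 19.8 ± 0.721 against 2.09 ± 0.360 CPM. Lysosome and iron genes were 13 higher and 2 lower of 16 (median 0.57, camera adjusted p = 7.18e-05; adjusted p = 0.0302 with an estimated correlation). The protease gene Ctsl was at 2120 ± 79.3 against 721 ± 5.41 CPM, and the transferrin receptor gene Tfrc at 426 ± 1.97 against 159 ± 3.17 CPM.

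Cell cycle genes were 22 lower and 3 higher of 30 (median -0.53, camera adjusted p = 4.05e-07; adjusted p = 0.194 with an estimated correlation), with Mki67 at 251 ± 5.90 against 877 ± 13.9 CPM and the cyclin gene Ccnb2 at 24.3 ± 2.32 against 132 ± 4.25 CPM. TGF-beta and BMP genes were 13 lower and 3 higher of 18 (median -0.98, camera adjusted p = 0.00056; adjusted p = 0.111 with an estimated correlation), with Thbs1, a matrix glycoprotein, at 17.9 ± 0.159 against 172 ± 1.51 CPM. Glycolysis and hypoxia genes were 22 lower and 7 higher of 30 (median -0.64, camera adjusted p = 0.00203; adjusted p = 0.491 with an estimated correlation), with Ldha at 1070 ± 31.5 against 2019 ± 57.7 CPM. Epithelial junction and keratin genes were 8 lower and 2 higher of 11 (median -0.86, camera adjusted p = 0.032; adjusted p = 0.187 with an estimated correlation), and the call was lost with library sizes alone (adjusted p = 0.0535, the highest over these settings). Complement genes were 10 lower and 0 higher of 11 (median -0.71, camera adjusted p = 0.0458; adjusted p = 0.36 with an estimated correlation). That call was lost without M0 CM 2 (0.0518), M0 CM 3 (0.0704) or TAM CM 1 (0.0565), and with library sizes alone (0.06). The mesenchymal filament gene Vim fell from 4634 ± 103 to 1704 ± 86.4 CPM and Krt8 from 267 ± 8.57 to 63.6 ± 2.27 CPM. The epithelial-mesenchymal transition list had 6 higher and 14 lower of 23 and no call (median -0.48, camera adjusted p = 0.0915).

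Immune genes went both ways. Cd274 rose from 0.504 ± 0.265 to 3.96 ± 0.207 CPM and H2-K1 from 234 ± 8.21 to 401 ± 13.8 CPM. The galectin gene Lgals9 fell from 56.0 ± 2.09 to 16.4 ± 0.862 CPM. No call was made for the interferon-gamma list (3 higher and 15 lower of 27), the type I interferon list (7 and 13 of 32), MHC class I (7 and 10 of 19), NF-kB and TNF (8 and 12 of 22, with a median of -0.18 and a mean of 0.36), chemokines and cytokines (13 and 9 of 27), STAT3 and acute phase (7 and 3 of 13), checkpoint ligands (5 and 4 of 11, with a median of -0.16 and a mean of 0.12), IL-4 and STAT6 (2 and 5 of 11), cancer stem cell markers (6 and 3 of 12) or oxidative phosphorylation (6 and 13 of 27). The camera adjusted p of oxidative phosphorylation was 0.0915 and passed with library sizes alone (0.0431, the lowest over these settings). Of the MHC class II list, Cd74, the class II invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), rose from 0.126 ± 0.0358 to 24.4 ± 1.84 CPM.

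This comparison had the most calls of those against M0 CM, with 5089 genes higher and 5067 lower by edgeR's quasi-likelihood test, 1317 and 1442 of them at least 2-fold apart. The groups did not overlap for 10603 genes, against 10% by chance. Camera called 11 lists, and 2 of these calls held with an estimated correlation. Adjusted over the list alone, the counts of the 23 lists were the same except for 1 more lower checkpoint gene. Among genes with no counts in M0 CM, Cox6a2, a muscle-type subunit of cytochrome c oxidase (ENSMUSG00000030785, chromosome 7, 128205435 to 128206387), reached 24.2 ± 2.03 CPM, at least 521-fold higher. Fgf21, a secreted metabolic hormone, rose from 0.172 ± 0.0761 to 78.3 ± 1.64 CPM, and Cdh26 fell from 88.1 ± 3.51 to 3.68 ± 0.584 CPM.

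**Figure D2:**
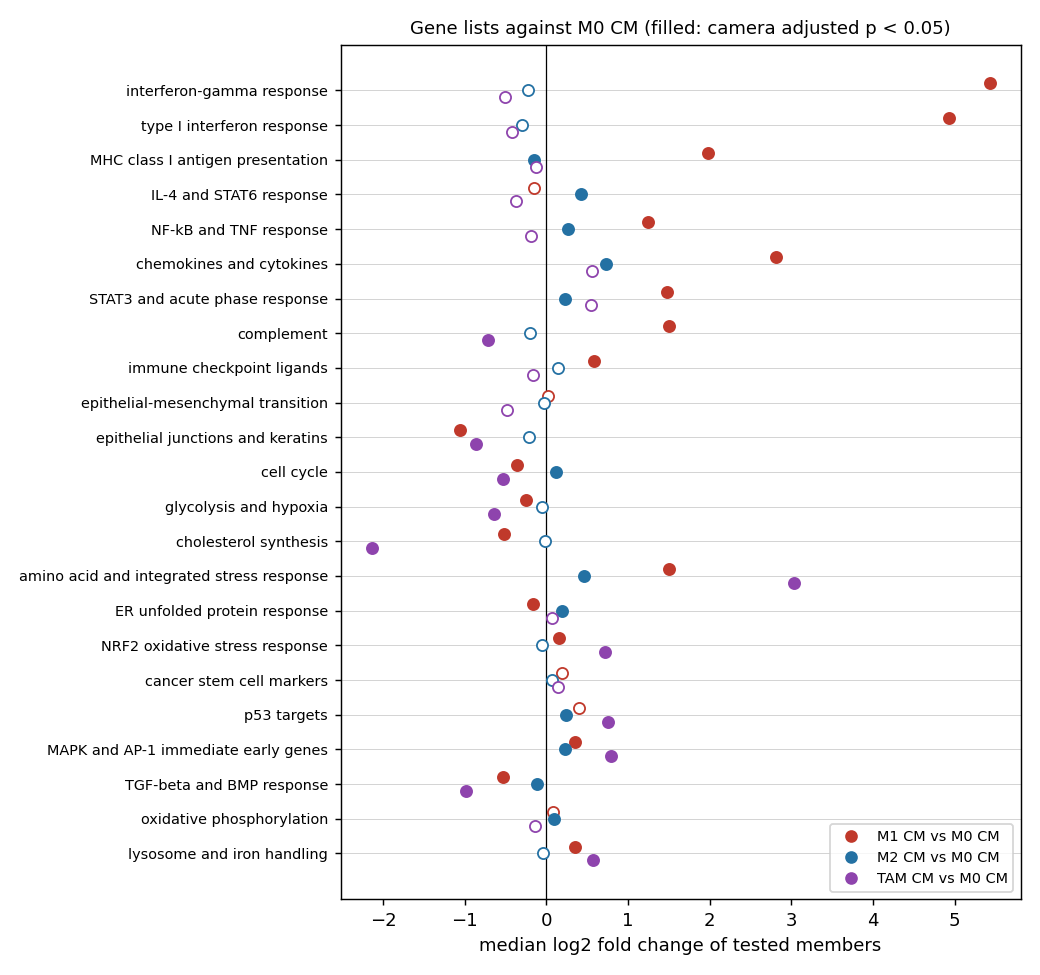
Median log2 fold change (x axis) of the tested members of 23 gene lists (y axis) in M1 CM, M2 CM and TAM CM against M0 CM, filled where the camera adjusted p with a preset correlation was under 0.05. The interferon-gamma list lies at 5.43 in M1 CM, and in TAM CM the amino acid list lies at 3.03 and the cholesterol list at -2.14; the medians of the epithelial-mesenchymal list in M1 CM and of the unfolded protein list in TAM CM change sign with library sizes alone.

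**Figure D3:**
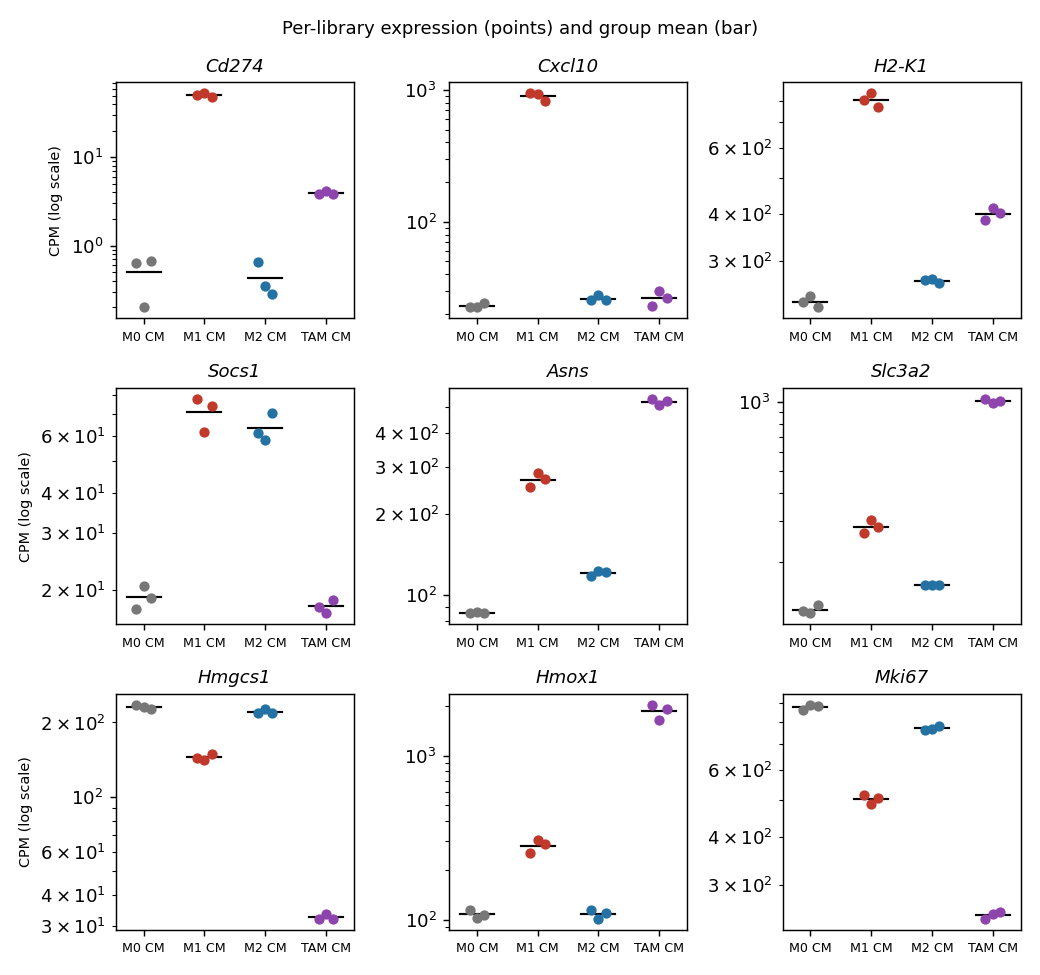
CPM on a log axis of 9 genes in the 12 libraries, each point a library and each bar the mean of 3 libraries, by medium. Cd274, Cxcl10 and H2-K1 are highest in M1 CM, Asns, Slc3a2 and Hmox1 are highest in TAM CM, Hmgcs1 and Mki67 are lowest in TAM CM, and Socs1 stands at 71.2 CPM in M1 CM and 63.3 in M2 CM.

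The treated groups were also compared with each other. Between TAM CM and M1 CM, the interferon genes separated the groups most. Gbp4 was at 17.7 ± 0.676 CPM in TAM CM and 2138 ± 39.7 in M1 CM. All 27 interferon-gamma genes were lower in TAM CM (median -5.44, camera adjusted p = 1.88e-21), as were all 32 type I interferon genes (median -5.11, camera adjusted p = 1.65e-21) and all 19 MHC class I genes (median -2.04, camera adjusted p = 1.66e-16). Amino acid and integrated stress genes were higher in TAM CM, 25 of 25 (median 1.57, camera adjusted p = 2.48e-19; adjusted p = 0.0596 with an estimated correlation), with Atf3, a stress-induced transcription factor, at 66.9 ± 0.791 against 5.70 ± 0.594 CPM. All 22 cholesterol genes were lower (median -1.65, camera adjusted p = 1.18e-15; adjusted p = 0.0164 with an estimated correlation).

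Of the other lists called between these groups, NF-kB and TNF genes were 19 lower and 2 higher of 22 in TAM CM (camera adjusted p = 7.26e-08) and chemokines and cytokines 21 lower and 2 higher of 27 (camera adjusted p = 6.52e-06). The remaining calls did not hold with an estimated correlation. Complement was 10 lower and 1 higher of 11 (camera adjusted p = 8.38e-05; adjusted p = 0.0596 with an estimated correlation) and STAT3 genes 9 lower and 3 higher of 13 (0.00537; adjusted p = 0.0674 with an estimated correlation). Unfolded protein genes were 12 higher and 1 lower of 18 (camera adjusted p = 7.4e-05; adjusted p = 0.107 with an estimated correlation) and p53 targets 13 higher and 4 lower of 18 (0.00111; adjusted p = 0.107 with an estimated correlation). NRF2 genes were 14 higher and 2 lower of 20 (camera adjusted p = 0.00129; adjusted p = 0.37 with an estimated correlation) and cell cycle genes 18 lower and 11 higher of 30 (0.0316; adjusted p = 0.398 with an estimated correlation). Adjusted over the list alone, the counts of the lists called were the same, with 2 more lower NRF2 genes. Among lists not called was TGF-beta, lower (camera adjusted p = 0.0558). It passed without M1 CM 1 (0.0451), 2 (0.0254) or 3 (0.0483), and without TAM CM 1 (0.0499) or 3 (0.0488). The epithelial-mesenchymal list (lower, 0.062) passed without M1 CM 2 (0.0448) or TAM CM 1 (0.0499). MAPK genes (higher, 0.062) passed without M1 CM 3 (0.0257) or TAM CM 2 (0.0458). Checkpoint ligands (lower, 0.0849) passed without M1 CM 1 (0.0484). By edgeR's quasi-likelihood test 4755 genes were higher and 4997 lower in TAM CM than in M1 CM, 832 and 1354 of them at least 2-fold apart, and 10085 did not overlap, against 10% by chance. Cd274 was at 3.96 ± 0.207 CPM in TAM CM and 51.4 ± 2.59 in M1 CM.

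Between TAM CM and M2 CM the same metabolic genes stood apart. Slc3a2 was at 1005 ± 20.7 CPM in TAM CM and 158 ± 0.218 in M2 CM, and 24 of 25 amino acid and stress genes were higher, none lower (median 2.67, camera adjusted p = 5.47e-20; adjusted p = 0.0912 with an estimated correlation). All 22 cholesterol genes were lower (median -2.08, camera adjusted p = 1.54e-16; adjusted p = 0.0264 with an estimated correlation). The interleukin-4 marker Il13ra2 was at 1.16 ± 0.395 CPM in TAM CM and 12.8 ± 0.212 in M2 CM, and IL-4 and STAT6 genes were 8 lower and 1 higher of 11 (median -1.37, camera adjusted p = 0.0132; adjusted p = 0.121 with an estimated correlation). Krt8 was at 63.6 ± 2.27 CPM in TAM CM and 453 ± 20.5 in M2 CM, and Nfkb1 at 122 ± 1.21 and 568 ± 1.77 CPM.

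Calls that held with an estimated correlation were cholesterol, lysosome (14 higher and 2 lower of 16; camera adjusted p = 2.16e-05) and TGF-beta (13 lower and 3 higher of 18; camera adjusted p = 0.0014). Cell cycle genes were 27 lower and 2 higher of 30 in TAM CM (camera adjusted p = 5.07e-11; adjusted p = 0.0912 with an estimated correlation) and glycolysis genes 23 lower and 6 higher of 30 (0.00113; adjusted p = 0.45 with an estimated correlation). NRF2 genes were 17 higher and 2 lower of 20 (camera adjusted p = 7.56e-07; adjusted p = 0.276 with an estimated correlation), p53 targets 12 higher and 4 lower of 18 (0.0132; adjusted p = 0.251 with an estimated correlation) and MAPK genes 14 higher and 5 lower of 25 (0.0206; adjusted p = 0.45 with an estimated correlation). Oxidative phosphorylation genes were 17 lower and 6 higher of 27 (camera adjusted p = 0.0132; adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, the called lists had the same counts but for 1 more lower cell cycle gene. Without the third M2 CM library camera also called NF-kB and TNF lower (adjusted p = 0.0415 in place of 0.0606). It then also called epithelial junctions lower (0.0433 in place of 0.0606) and cancer stem cell markers higher (0.0415 in place of 0.0692). Without TAM CM 2 these lists passed too (0.0495, 0.0495 and 0.0336), and the stem cell list passed without TAM CM 1 (0.0491). In edgeR's quasi-likelihood test 4974 genes were higher and 4945 lower in TAM CM than in M2 CM, 1303 and 1216 at least 2-fold, and 10351 did not overlap, against 10% by chance.

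M2 CM and M1 CM differed most in interferon genes, 25 of 27 on the interferon-gamma list and all 32 on the type I list being lower in M2 CM (medians -5.67 and -5.17, camera adjusted p = 1.01e-27 and 6.53e-30). All 19 MHC class I genes were lower too (median -2.18, camera adjusted p = 2.46e-24), with B2m at 536 ± 6.13 against 2427 ± 60.3 CPM. Genes that were higher in M2 CM included Ces1g, at 101 ± 7.06 against 0.765 ± 0.508 CPM, and Il24, at 54.8 ± 2.48 against 0.490 ± 0.334 CPM. Cell cycle genes were 29 higher and 0 lower of 30 (median 0.49, camera adjusted p = 9.54e-16), and Mki67 was at 773 ± 10.3 against 504 ± 12.9 CPM.

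Lower in M2 CM than in M1 CM were also NF-kB and TNF genes (17 lower and 3 higher of 22, camera adjusted p = 4.95e-08), chemokines and cytokines (20 and 3 of 27, 3.33e-06), STAT3 genes (10 and 1 of 13, 3.86e-06) and lysosome genes (12 and 2 of 16, 3.44e-06). Amino acid and stress genes were 24 lower and 0 higher of 25 (camera adjusted p = 9.54e-16; adjusted p = 0.0689 with an estimated correlation) and complement genes 9 lower and 2 higher of 11 (0.000683; adjusted p = 0.0689 with an estimated correlation). NRF2 genes were 14 lower and 3 higher of 20 (camera adjusted p = 0.000221; adjusted p = 0.343 with an estimated correlation) and checkpoint ligands 5 lower and 1 higher of 11 (0.0253; adjusted p = 0.0689 with an estimated correlation). Higher in M2 CM were cholesterol genes (17 of 22 and none lower, camera adjusted p = 1.3e-07; adjusted p = 0.0563 with an estimated correlation), unfolded protein genes (14 higher and 2 lower of 18, 8.33e-06; adjusted p = 0.0689 with an estimated correlation) and glycolysis genes (15 and 6 of 30, 0.0118; adjusted p = 0.567 with an estimated correlation). Adjusted over the list alone, 1 more gene was lower on each of the NF-kB, chemokine, STAT3 and NRF2 lists, and 2 more glycolysis genes and 1 more NRF2 gene were higher. By edgeR's quasi-likelihood test 4036 genes were higher and 4121 lower, 323 and 979 at least 2-fold, and 8683 did not overlap, against 10% by chance.

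Calls against M0 CM were shared between the treated groups. M1 CM and TAM CM shared 2499 higher and 2570 lower genes, where independent lists of those lengths would share 1411 and 1299, and 1246 genes were called in opposite directions. M1 CM and M2 CM shared 1296 higher and 1238 lower genes (843 and 687 for independent lists), with 1357 opposite. M2 CM and TAM CM shared 1753 higher and 1646 lower genes (1067 and 936 for independent lists), with 1331 opposite. In 20 simulated data sets with no group differing from M0 CM, no call was shared, a value that holds with no effect and gives no expectation for lists of these lengths. The covariance of the log2 fold changes across genes was 0.101 for M1 CM and M2 CM, 0.433 for M1 CM and TAM CM and 0.149 for M2 CM and TAM CM, beside simulated covariances of 0.0148, 0.0147 and 0.0147 from the shared M0 CM libraries. The correlations across genes were 0.217, 0.434 and 0.269, beside 0.496, 0.488 and 0.490 simulated. These simulated correlations come from the shared M0 CM libraries with no effect, and are no measure for groups that differ. The 3 M0 CM libraries are too few for 2 sets of 2 and were not split, so part of the excess may come from sharing them. No count for independent lists was worked out for the opposite calls. How far the excess reflects genes called in both comparisons whatever their direction was not tested.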

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

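Among the alternatives, only the library sizes without scaling factors were chosen after results were seen. No named gene called by the edgeR test changed direction. Of 6317 values of named genes under alternatives, 6263 kept direction and side of the threshold. The counts of genes called stayed within 1.5 times under every alternative but glmTreat, which tests for more than a 1.5-fold change and so calls fewer by construction. It called 920 genes higher and 452 lower in M1 CM against M0 CM, 201 and 175 in M2 CM, and 1871 and 1941 in TAM CM. It called 1266 and 1716 for TAM CM against M1 CM, 1756 and 1666 for TAM CM against M2 CM, and 387 and 1026 for M2 CM against M1 CM. With an estimated correlation camera called 1 list in M2 CM against M0 CM, 2 in TAM CM against M0 CM, 6 in TAM CM against M1 CM, 3 in TAM CM against M2 CM and 8 in M2 CM against M1 CM. With library sizes alone TAM CM against M0 CM had 4300 genes higher and 5891 lower, where TMM gave 5089 and 5067. Fry tests whether the genes of a list shifted together, without weighing them against other genes. It called 21, 23 and 22 lists for TAM CM against M0 CM, M1 CM and M2 CM.

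Leaving out single libraries turned the sign of the log2 fold change of 4 named genes, none of which passed the test with all libraries, and the cause was not tested. Lowest and highest values were -2.63 and 1.87 for S100a8 and -0.0337 and 0.0559 for Hmox1 in M2 CM against M0 CM, -0.0207 and 0.186 for Mitf in TAM CM against M1 CM, and -0.0678 and 0.116 for Cxcl10 in TAM CM against M2 CM. With the replicate block, 7806 genes were called in M1 CM against M0 CM where 7742 were called without it, and 10184 where 10156 were called in TAM CM. Of the list calls it changed 1, oxidative phosphorylation lower in TAM CM than in M1 CM, from a camera adjusted p of 0.0558 to 0.0498. This list also passed with library sizes alone (0.0384) and without M1 CM 3 (0.0257) or TAM CM 1 (0.0499). Of named genes, the block brought 2 under the threshold of edgeR's test. Socs1 in M2 CM against M1 CM (adjusted p = 0.0307) also passed without M1 CM 2 (0.000226) or M2 CM 3 (0.00557). Mitf in M2 CM against M0 CM (0.0364) also passed without M0 CM 2 (0.0281) or M2 CM 1 (0.0211). It passed too with DESeq2 size factors in the edgeR fit (0.0462) and in a fit of these 2 groups only (0.0367). Residual correlations of libraries with the same number ran from -0.0289 to 0.0507, with 0 of 18 over 0.1. Still, 10 of 12 libraries correlated best with their own number out of 3, where chance gives about 1 in 3. This points to a small effect shared by number, and its source was not tested.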

Other observations

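The genes and tests in this part were chosen after results were seen, except for the splits and the GC content and length, glucose and sterol tests. How the glucose and sterol tests treat genes that did not pass or could not be tested was settled after their values were seen. Of the genes of amino acid supply, Asns stood at 85.7 CPM in M0 CM, 120 in M2 CM, 268 in M1 CM and 523 in TAM CM, and Slc3a2 at 123, 158, 284 and 1005 CPM. Cd74, the class II invariant chain, reached 24.4 CPM in TAM CM with 0 CPM of the class II gene H2-Aa and 0 CPM of the class II activator Ciita. Ces1g went in opposite directions, to 101 CPM in M2 CM and 0.765 CPM in M1 CM from 5.07 CPM in M0 CM. In M0 CM the cells held Vim at 4634 CPM and Col1a2 at 1475.5 CPM beside Krt8 at 267 CPM, with 0 CPM of Epcam.

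The rise of the integrated stress response list in TAM CM (camera adjusted p = 3.49e-19; adjusted p = 0.111 with an estimated correlation) was weighed against 4 explanations. A trend on GC content and gene length explained 0.897% of the variance of the log2 fold changes, and removing it left a median of 3.06 (3.03 before), which speaks against such a bias as the whole cause. The 6 abundant macrophage genes were Lyz2, Tyrobp, Fcer1g, C1qa, C1qb and C1qc. They summed to 1.33 CPM in TAM CM, nearly all of it Lyz2 (1.31 CPM, and 0.831 CPM in M0 CM). Tyrobp, C1qa, C1qb and C1qc had 0 CPM in every group, so macrophage RNA carried over is an unlikely source. The macrophage marker list, at 51.6 CPM in TAM CM, was mostly Cd14. Nutrients used up in medium that SCC7 cells had conditioned could give the list's median of 3.03, and no medium of SCC7 cells alone is held to compare. A glucose shortage would lower Txnip, which rose from 4.17 to 47.5 CPM (log2 fold change 3.51, SE 0.104). Arrdc4 had too few counts to test. The prediction written beforehand asked for both genes. The rise of Txnip alone, in a group where many stress genes rose, does not decide for or against a shortage.

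The rise of the interferon-gamma list in M1 CM kept a median log2 fold change of 3.65 over the 14 members outside families with shared reads, which speaks against reads shared between paralogs. The 6 macrophage genes summed to 0.537 CPM in M1 CM, against macrophage RNA. Interferon-gamma left in the medium could give the median of 5.43, and no library here had interferon-gamma alone. None had interleukin-4 alone either, so interleukin-4 left in M2 CM stays open for the rises there and was not tested.

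The fall of the cholesterol synthesis list in TAM CM kept a median of -2.06 (-2.14 before) after the same trend, which explained 0.897% of the variance, was removed, against such a bias as the whole cause. Sterol excess would raise the liver X receptor targets Abca1, Abcg1 and Mylip, whose median log2 fold change was -0.57. That median is the value of Abcg1 (SE 0.502, 0.306 against 0.444 CPM), and neither it nor Abca1 (-0.25, SE 0.213) passed the test. Mylip fell from 15.8 to 9.39 CPM (-0.74, SE 0.105, edgeR adjusted p = 2.08e-08), and only this gene speaks against sterol excess. SCC7 medium left in TAM CM stays open for this fall too and was not tested.

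The 6 libraries of each comparison make 10 splits, the real one included, too few for a share under 0.05. For genes the real grouping ranked 1 of 10 in every comparison. It called 7742 genes in M1 CM against M0 CM, 5723 in M2 CM, 10156 in TAM CM, 9752 for TAM CM against M1 CM, 9919 for TAM CM against M2 CM and 8157 for M2 CM against M1 CM, and the highest other split called 0, 0, 1, 0, 0 and 0. For gene lists the real counts in the same order were 18, 12, 11, 13, 11 and 15 and the highest others 16, 10, 10, 13, 10 and 14, with values of 1, 1, 1, 2, 1 and 1 of 10. Each mixed split sets 2 libraries of a group and 1 of the other against the reverse, so it keeps part of the real difference and gives no value for no change.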
